A study of Mus musculus with 16 samples.

How the data were processed

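Total RNA from the luminal population of mouse mammary glands, isolated by fluorescence-activated cell sorting, was measured on 16 Affymetrix mouse genome arrays of the perfect-match type. The deposited values are log2 signals, 1 per probe set and array, made by RMA per the submitters' processing notes; the RMA version, its settings and any later correction are not given in the sources used here. RMA corrects background, quantile-normalises and summarises probes, so absolute transcript amounts and differences in total RNA between groups cannot be read from these values. The table held 45141 probe sets, with values from 2.20 to 13.09 and array medians from 4.63 to 4.88. Pairwise correlations between arrays ran from 0.885 to 0.990, and 0 pairs were identical. The number of arrays limits the precision.

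The annotation table listed 29449 of the probe sets. Of these, 28898 carried exactly 1 gene symbol and 551 carried several, and the latter were left out; the other 15692 probe sets have no name in the sources used here and were not used. By Entrez gene ID, 28689 single-symbol probe sets matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols, and the remaining 209 kept the symbol of the annotation. Each gene was represented by its probe set with the highest mean over the 16 arrays. Of 17097 genes, the 14410 at or above the 25th percentile of all probe sets (3.67 on the log2 scale) were tested.

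The labels define 4 groups of 4 arrays. MMTV-Cre arrays and p38α-lox, MMTV-Cre arrays came from mice of 9 weeks. MMTV-Cre, MMTV-PyMT arrays and p38α-lox, MMTV-Cre, MMTV-PyMT arrays came from mice of 6 weeks. The labels do not state that each array is a separate animal and give no batch or pairing, so every p measures the spread between these samples. Replicate numbers have no order.

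Gene comparisons used limma 3.58.1 in R 4.3.3, with 1 linear model over all 16 arrays (12 residual degrees of freedom, 2.83 prior degrees of freedom) and moderated two-sided contrasts. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. Errors after ± are the standard error for log2 differences and the standard deviation of 4 arrays for group means. The contrasts were p38α-lox against its control without PyMT, the same with PyMT, the difference between these effects (the interaction), and PyMT against no PyMT without and with p38α-lox.

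Sets of genes were compared with camera in limma, with the preset inter-gene correlation of 0.01, over 34 lists of at least 5 tested genes covering mammary cell states, other cell types and cellular programmes; 498 of their 586 distinct genes were tested. Beside camera stand camera with a correlation estimated from the data, the rotation test fry, and an exact two-sided permutation test of each array's list mean, whose smallest p with 4 arrays against 4 is 0.0286. The lists, contrasts, tests, thresholds and most alternatives were fixed before the data were examined. Genes named in the text are the targeted gene Mapk14, Runx1, up to 10 called genes with the largest change in each direction whose arrays did not overlap (5 with the smallest p where fewer were called), and up to 4 members with the smallest p from each list described. For the interaction they are the 3 genes with the smallest p in each direction. Transcripts without an established gene name were passed over.

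The procedure was tested on simulated data of the same size. With 50 genes changed at each fold, 64.0% of 2-fold changes and 86.0% of 4-fold changes were called in the comparison of p38α-lox without PyMT, and 60.0% and 90.0% in the one with PyMT. Of 1.5-fold changes, 20% and 18% were called. Genes were simulated with independent noise, which real arrays do not have. Many genes were changed at once, which eases the adjusted threshold, so with few true changes the shares could be lower.

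Alternatives were no filter, a stricter filter at the median, the mean of all probe sets of a gene, eBayes with trend and robust options, a second quantile normalization, centring each array on its median, limma arrayWeights, fitting only the arrays compared, a minimum change of 2-fold, and leaving out each array in turn. Chosen after seeing the data were a fit without the 2 arrays of lowest median correlation with the others (p38α-lox replicate 2 and PyMT replicate 4) and a fit with a covariate for the numbers in the sample titles. These numbers fall into a lower range of 9 arrays and a higher range of 7, and their meaning is not given in the sources used here. Between the ranges 16 genes were called by limma, with 2207 at an unadjusted p under 0.05 where 720 would be expected by chance.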

Results

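Gene expression was profiled in sorted luminal mammary epithelial cells to compare mice with and without a floxed p38α allele. MMTV-Cre expresses Cre recombinase in mammary epithelium, and MMTV-PyMT drives mammary tumours through the polyoma middle T antigen. Of the 4 groups, each with 4 arrays, those without PyMT were from mice aged 9 weeks and are called MMTV-Cre and p38α-lox below. Those with PyMT were from mice aged 6 weeks and are called PyMT and p38α-lox PyMT. Array medians lay between 4.63 and 4.88 on the log2 scale. The first principal component of the tested genes held 28.1% of the variance and the second 15.5%.

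**Figure D1:**
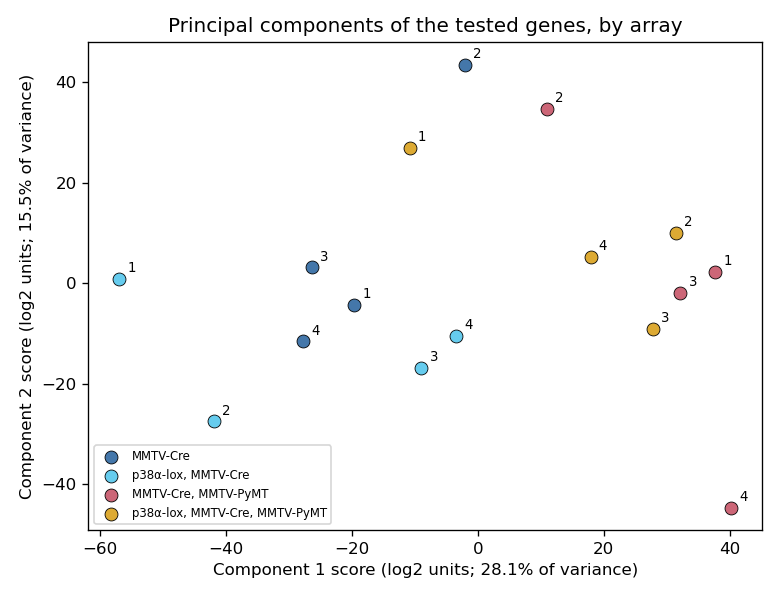
Scores of the 16 arrays on the first principal component (x axis, log2 units, 28.1% of variance) and the second (y axis, log2 units, 15.5% of variance), with colour for the group and the number beside each point for the replicate. Most PyMT and p38α-lox PyMT arrays have higher scores on the first component than the MMTV-Cre and p38α-lox arrays, and the groups with and without p38α-lox are mixed on both.

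The comparison of p38α-lox with MMTV-Cre asks what p38α, a stress-activated kinase encoded by Mapk14, does in luminal cells without the oncogene. Genes of the unfolded protein response, which fold and clear proteins in the endoplasmic reticulum, had lower estimates in p38α-lox arrays for all 18 measured members (list mean 8.40 ± 0.144 against 9.12 ± 0.459). Glycolysis and hypoxia genes had lower estimates for 17 of 18 members (8.90 ± 0.185 against 9.45 ± 0.245). Both lists passed camera with the preset correlation, but neither with an estimated correlation (adjusted p = 0.291 and 0.437) nor with fry (adjusted p = 0.275 and 0.444). No single gene passed the threshold over all genes, although the growth-factor-induced transcription factors Egr1 and Egr2 had log2 differences of 2.75 ± 0.452 and 2.09 ± 0.379. Both belong to the immediate early genes, which also respond to the stress of cell isolation.

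Within the unfolded protein response list, 4 members were lower when adjusted over the list alone and 0 when adjusted over all genes by limma. The examples are Hspa5, the main chaperone of the endoplasmic reticulum (−1.09 ± 0.337), Sdf2l1, part of an Hspa5 chaperone complex (−1.56 ± 0.482), the calcium-binding chaperone Calr (−0.52 ± 0.156) and Edem1, which directs misfolded glycoproteins to degradation (−1.24 ± 0.412). The mean log2 difference of the list was −0.72, with camera adjusted p = 1.03e-11 but adjusted p = 0.291 with an estimated correlation. All 4 p38α-lox arrays lay below all 4 MMTV-Cre arrays (exact permutation p = 0.0286, reached by 2 of the 34 lists; the smallest adjusted exact permutation p was 0.486). The highest p38α-lox mean was 8.581 and the lowest MMTV-Cre mean 8.645. Within the lower and the higher range of title numbers, with 2 arrays against 2 in each, the differences of the list mean were −0.61 and −0.83.

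Of the glycolysis and hypoxia list, 8 members were lower when adjusted over the list alone and 0 over all genes. They include the angiogenic factor Vegfa (−1.35 ± 0.313), the phosphofructokinase Pfkl (−0.78 ± 0.183), the lactate dehydrogenase Ldha (−0.51 ± 0.134) and the vasodilator peptide Adm (−1.29 ± 0.387). The list mean differed by −0.55, with camera adjusted p = 1.27e-10 and adjusted p = 0.437 with an estimated correlation. The arrays of the groups did not overlap (exact permutation p = 0.0286), but narrowly. The highest p38α-lox mean was 9.17 and the lowest MMTV-Cre mean 9.173. The differences within the title ranges were −0.68 and −0.42.

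A further 4 lists passed camera with the preset correlation, each with adjusted p = 0.907 with an estimated correlation and 0 members called over the list alone. Markers of hormone-sensing luminal cells, such as the progesterone receptor Pgr (−1.26 ± 0.675) and Wnt5a (−1.65 ± 0.802), were lower by camera in 12 of 14 members (mean −0.70, adjusted p = 0.0075). This rested on MMTV-Cre replicate 2, without which the mean was −0.16 (adjusted p = 0.63; range over all alternatives 3.56e-05 to 0.907); without MMTV-Cre replicate 4 it was −1.05. Inflammatory NF-kB genes were higher in 18 of 20 members (mean 0.42, adjusted p = 0.0136), among them the chemokine Cxcl1 (1.58 ± 0.679) and the inhibitor Nfkbie (1.17 ± 0.46), while the prostaglandin synthase Ptgs2 had a difference of −1.41 ± 0.396. Their direction turned between the title ranges, with 0.985 in the lower and −0.149 in the higher one. Interferon-stimulated genes were higher in 13 of 17 (mean 0.25, adjusted p = 0.0278), with the RNA sensor Ifih1 at 0.96 ± 0.324. Cholesterol synthesis genes were lower in 11 of 15 (mean −0.31, adjusted p = 0.0352), with the sterol oxidase Msmo1 at −1.04 ± 0.371 and the reductase Dhcr7 at 1.40 ± 0.44. In the lower and higher title ranges the interferon list gave 0.24 and 0.26, the cholesterol list −0.49 and −0.12 and the hormone-sensing list −0.99 and −0.41.

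Single arrays decided the calls of the NF-kB, interferon and cholesterol lists. Without p38α-lox replicate 1, p38α-lox replicate 2 or MMTV-Cre replicate 4 these 3 calls ended, with adjusted p of 0.588, 0.393 and 0.0755 for the NF-kB list, 0.571, 0.0615 and 0.102 for the interferon list and 0.218, 0.573 and 0.136 for the cholesterol list. Without MMTV-Cre replicate 3 the interferon and cholesterol calls ended too (0.155 for each), and without MMTV-Cre replicate 1 the interferon call (0.106). The NF-kB mean was 0.22, 0.18 and 0.69 without p38α-lox replicates 1, 2 and 3. The interferon mean was 0.12 without MMTV-Cre replicate 3 or p38α-lox replicate 1 and 0.50 without MMTV-Cre replicate 2, and the cholesterol mean −0.20 and −0.16 without MMTV-Cre replicate 3 and p38α-lox replicate 2. Over all alternatives the adjusted p ran from 4.48e-06, 1.4e-05 and 0.0016 to 0.907 for the NF-kB, interferon and cholesterol lists.

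Limma called 0 of 14410 genes, with 690 at an unadjusted p under 0.05 where 720 would be expected by chance. The smallest adjusted p belonged to Irak1bp1, a partner of the IRAK1 signalling kinase, with 6.64 ± 0.122 in p38α-lox and 5.62 ± 0.265 in MMTV-Cre (adjusted p = 0.0603). Next came Egr1 (adjusted p = 0.154), the nuclear receptor coactivator Ncoa7 (1.97 ± 0.352), Egr2 and the kinase-binding protein Sh3bp5 (1.41 ± 0.259), the last 3 with adjusted p = 0.169. The lower genes with the smallest p were Atg13, which initiates autophagy (−0.71 ± 0.156, adjusted p = 0.419), Sar1a, a GTPase of vesicle export from the endoplasmic reticulum (−0.57 ± 0.129), Phf23 (−0.64 ± 0.151), Vegfa and Pfkl, each of these 4 with adjusted p = 0.479. Of the luminal progenitor markers, Aldh1a3, a retinaldehyde dehydrogenase, differed by −1.55 ± 0.416 and was the 1 member called when adjusted over the list alone, while the receptor Kit differed by 1.39 ± 0.517; the list was not shifted (camera adjusted p = 0.778). The transcription factor Runx1 differed by −0.02 ± 0.252. Without MMTV-Cre replicate 1, 4 genes were called, Egr1 (adjusted p = 0.00233) and Egr2 (0.0428) among them, and without MMTV-Cre replicate 4 the 1 called gene was Irak1bp1 (0.0321); over all alternatives the adjusted p of these genes ran from 0.00233, 0.0171 and 0.0188 to 0.935. Of the 34 lists 6 passed camera (9 at an unadjusted p under 0.05), and 3 without MMTV-Cre replicate 4. At least 6 passed in 21 of the 35 splits of these arrays into 4 and 4, so the number is not separable from chance, and 0 passed with an estimated correlation or with fry (2 each at an unadjusted p under 0.05).

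Mapk14 itself was read by 6 probe sets, of which 0 had a lower mean in p38α-lox than in MMTV-Cre and 5 a lower mean in p38α-lox PyMT than in PyMT. The probe set used gave 7.31 ± 0.862 against 6.53 ± 0.885 (exact permutation p = 0.257), and with PyMT 7.23 ± 0.103 against 7.20 ± 0.321 (exact permutation p = 0.886). Without PyMT the means hide opposite directions. In the lower title range p38α-lox replicates 1 and 2 (6.791 and 6.371) lay below MMTV-Cre replicates 1 and 2 (7.106 and 7.43), a difference of −0.69. In the higher range p38α-lox replicates 3 and 4 (7.906 and 8.159) lay above MMTV-Cre replicates 3 and 4 (5.555 and 6.024), a difference of 2.24. Of the 6 probe sets 3 turned in this way. The cell cycle list turned too, with −1.35 and 1.09 in the lower and higher range. All comparisons with arrays without PyMT rest on the genotype labels as given. Which part of the gene is deleted and where the probes lie are not given in the sources used here, so these values do not measure recombination.

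**Figure D2:**
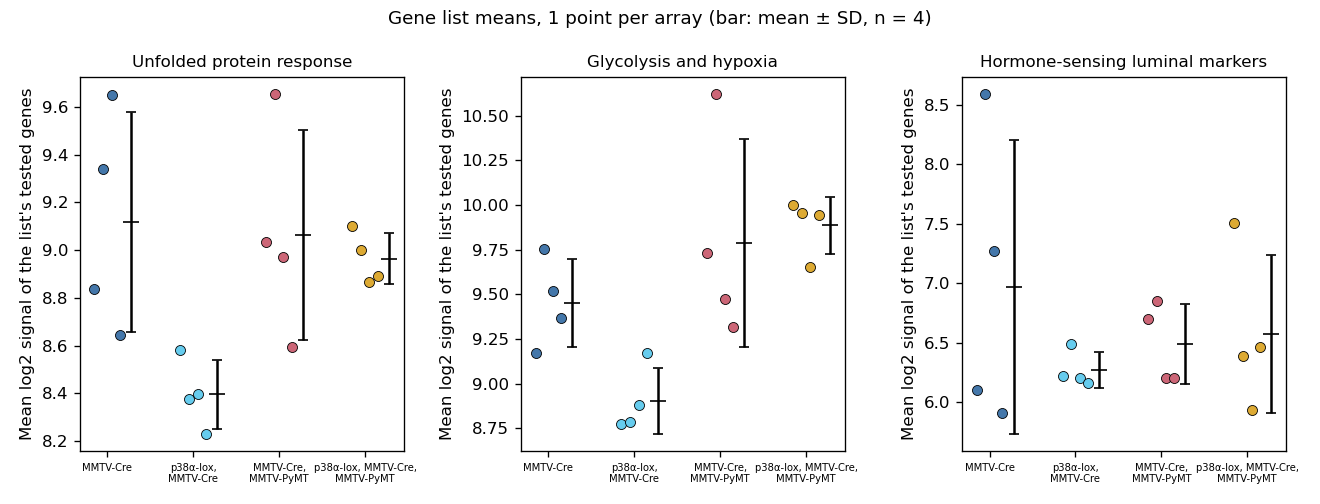
Mean log2 signal of the measured genes of the unfolded protein response, glycolysis and hypoxia, and hormone-sensing luminal lists (y axes) in each array, by group (x axis), with bars for the mean and standard deviation of 4 arrays. In the first and second panels every p38α-lox array lies below every MMTV-Cre array. The nearest arrays are at 8.581 and 8.645 in the first panel and at 9.17 and 9.173 in the second. In the third MMTV-Cre replicate 2 has the highest value, 8.59.

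The same comparison in PyMT mice asks what p38α does in luminal cells carrying the oncogene. Ribosomal protein genes had higher estimates in p38α-lox PyMT arrays for all 17 measured members, by a mean of 0.17 on the log2 scale (11.83 ± 0.0898 against 11.66 ± 0.183). This list passed camera with the preset correlation, but neither with an estimated correlation (adjusted p = 0.851) nor with fry (adjusted p = 0.541). Milk protein genes had lower values for Wap, the whey acidic protein (7.94 ± 0.371 against 9.53 ± 1.15), while their list did not pass. No single gene passed the threshold.

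The ribosomal list was called by camera (adjusted p = 1.75e-06), but with adjusted p = 0.851 with an estimated correlation, and its array means did not separate the groups (exact permutation p = 0.171). Examples are Rps9 (0.34 ± 0.136), Rps19 (0.42 ± 0.199) and Rps14 (0.30 ± 0.159), and 0 members were called when adjusted over the list alone. Without PyMT replicate 4 the mean was 0.08 (adjusted p = 0.00745; range over all alternatives 4.22e-09 to 0.851), and within the lower and higher title ranges it was 0.24 and 0.10, the latter with 1 PyMT array. The PyMT arrays also enter the comparison with MMTV-Cre, where this list was lower. It was the 1 list of 34 that passed camera with the preset correlation, and 0 passed with an estimated correlation or with fry; without PyMT replicates 2 and 4 and p38α-lox PyMT replicate 1 the number was 6, 4 and 9. In 34 of 35 splits at least 1 list passed, so a count of 1 list is not separable from chance. That count does not test the ribosomal list itself, whose exact permutation p was 0.171.

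Among milk and alveolar genes Wap differed by −1.59 ± 0.409 and was the 1 member called when adjusted over the list alone, and lactalbumin Lalba differed by −1.23 ± 0.706; the list did not pass (mean −0.28, camera adjusted p = 0.344), but did without PyMT replicate 2 (−0.53, adjusted p = 0.00987; range over all alternatives 0.00987 to 0.983), and the mean was −0.09 without PyMT replicate 1. Of the mammary transcription factors, Id2 differed by −0.68 ± 0.235 and Cebpb by −0.91 ± 0.353; their list (mean −0.21, adjusted p = 0.267) passed without PyMT replicate 4 (−0.28, adjusted p = 0.0334; range over all alternatives 0.0334 to 0.851). The neutrophil chemokine Cxcl2 differed by −1.88 ± 0.795, and the cell cycle gene Ccnd1 by 0.80 ± 0.301. The lists lower in p38α-lox without PyMT had mean differences of −0.10 for the unfolded protein response (camera adjusted p = 0.757) and 0.10 for glycolysis and hypoxia (camera adjusted p = 0.344) here. Without PyMT replicate 2 glycolysis passed upwards (0.38, adjusted p = 0.000295; range over all alternatives 0.000295 to 0.981), while without PyMT replicate 4 its mean was −0.06. Without PyMT replicate 2 the unfolded protein response list gave 0.10, against −0.26 without PyMT replicate 4.

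Limma called 0 genes in this comparison, with 516 at an unadjusted p under 0.05, and 3 genes, Trmt61b among them (adjusted p = 0.0407; range over all alternatives 0.0407 to 1), when PyMT replicate 2 was left out. The smallest p belonged to Syvn1, the ubiquitin ligase that clears proteins from the endoplasmic reticulum (5.40 ± 0.121 against 6.69 ± 0.384, adjusted p = 0.757). It was followed by the lower genes Nfatc2ip (−0.76 ± 0.153), the mitochondrial tRNA methyltransferase Trmt61b (−0.87 ± 0.2), the histone methyltransferase Setd1b (−1.003 ± 0.233) and histidine ammonia-lyase Hal (−0.94 ± 0.224). The higher genes with the smallest p were Nhsl2 (0.56 ± 0.145), the membrane skeleton protein Epb41l3 (1.20 ± 0.344), the splicing cofactor Snw1 (0.63 ± 0.182), the zinc finger gene Zfp292 (0.97 ± 0.296) and Mospd2 (0.58 ± 0.177), each with adjusted p = 0.999. Runx1 differed by 0.25 ± 0.252.

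Whether the p38α-lox difference depended on PyMT was tested as the interaction. Arrays with PyMT were from mice of 6 weeks and the others from mice of 9 weeks, so PyMT and age cannot be told apart here. Unfolded protein response and glycolysis genes had a higher p38α-lox difference with PyMT than without, by 0.62 and 0.65 (camera adjusted p = 1.63e-06 and 3.94e-09). Both had adjusted p = 0.691 with an estimated correlation. In all, 10 lists passed camera, 7 upwards and 3 downwards, the latter being the NF-kB (−0.78), milk (−0.54) and interferon (−0.37) lists. With each of the 16 arrays left out in turn, the unfolded protein response and glycolysis lists passed in all 16 fits (0.45 to 0.82 and 0.50 to 0.93), the NF-kB list in 13, the milk list in 11 and the interferon list in 7. The value was −0.24 for milk without MMTV-Cre replicate 2 and −0.19 for interferon without PyMT replicate 1. Without PyMT the p38α-lox difference turned between the lower and higher title ranges for NF-kB (0.985 and −0.149) and milk (0.75 and −0.219). With an estimated correlation or with fry 0 lists passed. Of 100 groupings, the real one included, 18 gave at least 10. The others were random over all 16 arrays and mixed arrays with and without PyMT. The PyMT difference can enter them, so they are no clean reference for the interaction. Limma called 0 genes for the interaction, with 406 at an unadjusted p under 0.05. The genes with the smallest p were Sar1a (0.66 ± 0.183), the mitochondrial carrier Slc25a33 (1.14 ± 0.326) and Ubap1 (1.07 ± 0.311) upwards and Trim65 (−1.22 ± 0.251), Irak1bp1 (−0.96 ± 0.204) and the stanniocalcin Stc1 (−0.87 ± 0.197) downwards, each with adjusted p = 0.992. Across genes, which are not independent replicates, the p38α-lox differences without and with PyMT had a Pearson correlation of 0.103 and a Spearman correlation of 0.0448, and 49.4% of genes had the same sign.

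The comparison of PyMT with MMTV-Cre arrays shows what accompanied the oncogene, together with the age difference of 6 against 9 weeks, from which it cannot be told apart. The acute-phase protein Saa1 rose the most, from 5.59 ± 0.886 to 10.73 ± 0.405, and its relative Saa2 rose by 3.83 ± 0.828. The milk protein genes Wap (3.35 ± 0.409) and Lalba (3.21 ± 0.706), the basal transcription factor Trp63 (2.21 ± 0.39) and the growth-factor-induced genes Egr1 (2.59 ± 0.452) and Fosl1 (2.21 ± 0.393) rose too. Egr1 and Fosl1 belong to the immediate early genes, which also respond to the stress of cell isolation. That stress was not tested in this comparison. With the mean of all its probe sets Trp63 differed by 1.05, and its call ended without PyMT replicate 1 (2.03, adjusted p = 0.058; range over all alternatives 0.00436 to 0.058). Pdk4, a kinase that holds back pyruvate oxidation, fell by 2.79 on the log2 scale, and the luminal progenitor marker Aldh1a3 by 1.85. The luminal progenitor list did not fall with it. Its mean difference was 0.05 to 0.34 over all alternatives, and the list was not called as reported. It passed camera upwards without MMTV-Cre replicate 3 (0.32, adjusted p = 0.0331). Limma called 182 genes, 127 higher and 55 lower, of which 150 changed at least 2-fold.

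The largest increases also included Col9a1, a collagen of cartilage (4.24 ± 0.504, adjusted p = 0.0018), the carbonic anhydrases Car12 (4.201 ± 0.471, adjusted p = 0.00117) and Car6 (3.71 ± 0.764), and S100a8, a calcium-binding protein of inflammation (4.16 ± 0.597, adjusted p = 0.005). The secretoglobin Scgb2b27 (4.02 ± 0.678), the lipogenic regulator Thrsp (3.97 ± 0.71), the amino acid oxidase Lao1 (3.88 ± 0.714) and the chemokine Cxcl2 (3.85 ± 0.795) rose by similar amounts. Among called genes whose arrays did not overlap, the largest decreases were those of Pdk4 (adjusted p = 0.00869), Ecscr, an endothelial surface protein (−2.78 ± 0.46, adjusted p = 0.0111), Armcx2 (−1.87 ± 0.426) and Aldh1a3 (adjusted p = 0.0437). Ovol2, a repressor that maintains epithelial identity (−1.72 ± 0.382), Mapk12, which encodes p38γ (−1.72 ± 0.385), the receptor adaptor Grb7 (−1.70 ± 0.299), Armcx6 (−1.69 ± 0.326), the splicing factor Slu7 (−1.66 ± 0.327) and the transcription factor Cebpg (−1.61 ± 0.271) followed. Of 18 alternatives, the call ended in 10 for Armcx2 and Mapk12, 9 for Ovol2, 8 for Aldh1a3 and Lalba and 7 for Armcx6, Slu7, Car6, Cxcl2 and Saa2. For the other genes named so far in this comparison it ended in at most 3. Runx1 differed by 0.37 ± 0.252 and Mapk14 by 0.67 ± 0.416, neither past the threshold.

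**Figure D3:**
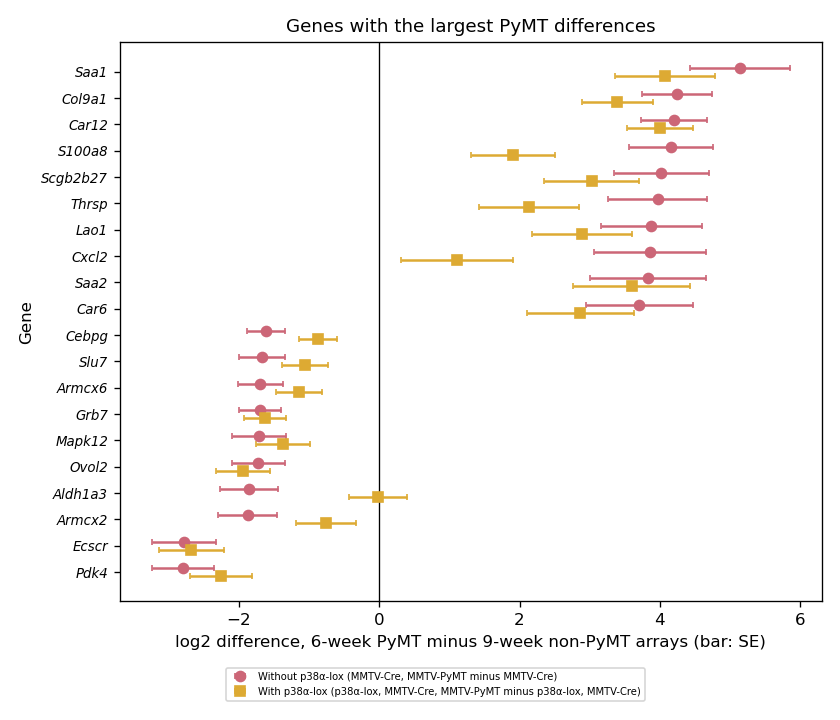
Log2 differences between arrays with and without PyMT (x axis, bars: standard error) for 20 genes (y axis), without p38α-lox (circles) and with it (squares). They are the 10 in each direction with the largest called changes without p38α-lox among named genes whose arrays did not overlap. The sign is the same in both comparisons for all 20 genes, and Aldh1a3 lies at −1.85 without p38α-lox and −0.02 with it.

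Markers of basal, milk-producing and stromal cells gave list differences that passed camera with the preset correlation, but neither with an estimated correlation nor with fry. Basal and myoepithelial markers, among them Snai2 (0.74 ± 0.157; call ended in 6 of 18 alternatives), had 2 members called, 6 when adjusted over the list alone and higher estimates in 11 of 14; the keratin Krt14 gave 2.54 ± 0.667 (adjusted p = 0.0784). The list mean differed by 0.94 (camera adjusted p = 0.000989; adjusted p = 0.634 with an estimated correlation). The difference was 0.98 within the lower title range and 1.03 within the higher one, with 1 PyMT array in the latter. Milk and alveolar genes differed by a mean of 0.82 (15 of 19 higher, 3 called, 5 over the list alone; camera adjusted p = 0.0018, and adjusted p = 0.735 with an estimated correlation). Mesenchymal transition genes differed by 0.48 (13 of 16 higher, 1 called, 4 over the list alone; camera adjusted p = 0.00566), with fibronectin Fn1 at 0.77 ± 0.205. Fibroblast markers differed by 0.68 (9 of 10 higher, 0 called, 2 over the list alone; camera adjusted p = 0.0044), with Postn at 1.80 ± 0.683 and Fbln1 at 0.88 ± 0.234. Both of the latter lists had adjusted p = 0.634 with an estimated correlation. The fibroblast mean of PyMT replicate 2 was 5.30, against 5.70 ± 0.491 in MMTV-Cre, and without that array the difference was 1.04; the lower and higher title ranges gave 0.31 and 1.36. The milk difference was 0.51 without MMTV-Cre replicate 2.

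Immediate early, fatty acid synthesis, inflammatory NF-kB and ribosomal protein genes likewise passed camera with the preset correlation, but neither with an estimated correlation nor with fry. Immediate early genes differed by a mean of 0.56 (6 members called, all higher, and 9 higher and 1 lower when adjusted over the list alone), with the nuclear receptor Nr4a1 at 1.99 ± 0.386 and Egr2 at 1.85 ± 0.379, whose calls ended in 5 and 7 of 18 alternatives. Fatty acid synthesis genes differed by 0.61 (3 called, 5 over the list alone), with the elongase Elovl5 at 1.25 ± 0.217 and the synthase Fasn at 1.84 ± 0.422 (call ended in 12 of 18 alternatives). Inflammatory NF-kB genes differed by 1.03 (4 called, 5 over the list alone), with Cxcl1 at 3.42 ± 0.679 (call ended in 6). The camera adjusted p of these lists were 0.00284, 0.00566 and 0.0119, and with an estimated correlation adjusted p = 0.634, 0.634 and 0.817. Ribosomal protein genes differed by a mean of −0.302 (16 of 17 lower, 0 called, 6 over the list alone), with Rps18 at −0.46 ± 0.113 and Rps9 at −0.53 ± 0.136 (camera adjusted p = 2.09e-07; adjusted p = 0.634 with an estimated correlation). Without MMTV-Cre replicate 2 the calls of the fatty acid (0.056), immediate early (0.0501), NF-kB (0.0636) and milk (0.228) lists ended, and without PyMT replicate 1 that of the NF-kB list (0.121). Over all alternatives the adjusted p of these lists ran from 0.00083 to 0.634, 0.000165 to 0.634, 0.00315 to 0.817 and 7.55e-06 to 0.735.

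The number of genes called depended on single arrays. It was 49, 443 and 76 without PyMT replicates 1, 2 and 4, and 90, 336, 86 and 63 without MMTV-Cre replicates 1 to 4. At least 182 genes were called in 1 of 35 splits, the real one, but at least 8 lists passed camera in 16 of them, so the number of lists is not separable from chance; 0 lists passed with fry or with an estimated correlation (7 and 2 at an unadjusted p under 0.05). The arrays of the groups did not overlap for 1022 genes, 7.09% of those tested, where chance gives 2.86%.

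With p38α-lox, the PyMT difference, again together with that of age, had much in common with the PyMT difference without p38α-lox. Limma called 112 genes, 79 higher and 33 lower, between p38α-lox PyMT and p38α-lox arrays, and 51 genes were called in both comparisons, all in the same direction (41 higher, 10 lower). Independent calls would give 0.696 higher and 0.126 lower in both. The 2 comparisons share 1 model and the same estimate of spread for each gene, so their calls are not independent and these numbers are a rough reference. Saa1 (4.08 ± 0.714), Col9a1 (3.39 ± 0.504) and Car12 (4.01 ± 0.471) rose again, and Pdk4 (−2.25 ± 0.444), Ecscr (−2.67 ± 0.46), Ovol2 (−1.94 ± 0.382) and Grb7 (−1.63 ± 0.299) fell again. Of the 182 genes called without p38α-lox, 179 had the same sign with it.

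Glycolysis and hypoxia genes had higher estimates in all 18 members, by a mean of 0.98 (camera adjusted p = 2.19e-14 and fry adjusted p = 0.0349, but adjusted p = 0.243 with an estimated correlation). Adm (2.46 ± 0.387), the carbonic anhydrase Car9 (2.68 ± 0.456), the platelet phosphofructokinase Pfkp (1.19 ± 0.218), the glucose transporter Slc2a1 (1.25 ± 0.244) and Vegfa (1.59 ± 0.313) were the 5 called members, and 11 were called over the list alone; genes named in this comparison beyond those above were chosen after their values were seen. Basal markers differed by 1.24 (13 of 14 higher, 0 called, 8 over the list alone; camera adjusted p = 1.65e-07, fry adjusted p = 0.0384, but adjusted p = 0.243 with an estimated correlation), and fibroblast markers by 0.78 (10 of 10; 0.00435, and adjusted p = 0.512 with an estimated correlation). Unfolded protein response genes differed by 0.57 (17 of 18 higher; 8.4e-05) and heat shock genes by −0.654 (11 of 11 lower; 0.000161), both with adjusted p = 0.512 with an estimated correlation, and with 5 and 3 members called over the list alone. Oxidative phosphorylation (0.34; 0.000542), cholesterol (0.57; 0.00336) and fatty acid synthesis (0.35; 0.0203) genes passed upwards by camera and ribosomal protein genes (−0.15; 0.0203) downwards, with adjusted p = 0.512, 0.512, 0.601 and 0.759 with an estimated correlation.

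The p38α-lox arrays also enter the comparison with MMTV-Cre, so their low glycolysis and unfolded protein response means are part of both results. The differences between these PyMT effects did not pass for any gene. Egr1 differed by 0.14 ± 0.452 with p38α-lox against 2.59 without it, Aldh1a3 by −0.02 ± 0.416 against −1.85 and the catalase Cat by −0.01 ± 0.224 against 1.28, each with an interaction adjusted p = 0.992. The count of 112 became 43 and 47 without p38α-lox replicates 1 and 3, and 194, 27, 26 and 29 without p38α-lox PyMT replicates 1 to 4. In 1 of 35 splits, the real one, at least 112 genes were called, and in 9 at least 9 lists passed camera, which is not separable from chance; fry called 2 lists and camera with an estimated correlation 0.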

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

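In this part the tests of a cell share, of array quality, of isolation stress and of 1 array alone, and the fit without the 2 arrays of lowest correlation, were chosen after the results were seen. Values of single arrays far from the other 3 of their group were looked for by Dixon's ratio in 136 groups of list means and 208 groups of named genes. This picked out 8 and 7, where chance would give 6.8 and 10.4.

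In MMTV-Cre replicate 2 the luminal progenitor list mean was 8.816 (others 9.594 to 9.632) and the oxidative phosphorylation mean 10.17 (9.933 to 9.963). In the same array Erbb4, a receptor of the EGF family, was at 5.244 (6.327 to 6.396) and the luminal transcriptional cofactor Lmo4 at 9.685 (11.67 to 11.88). In p38α-lox replicate 2 the endothelial (5.101; others 4.635 to 4.709), lymphocyte (5.184; 4.868 to 4.901) and myeloid (4.851; 4.369 to 4.44) means were higher than in the other 3. That array had the highest array median (4.879), the lowest array weight (0.206) and a low median correlation with the others (0.9339). The 3 means lie near its median, so other cells cannot be told apart from a property of the array. The class I antigen presentation mean was 9.027 in p38α-lox replicate 1 (9.409 to 9.466), where the progesterone receptor Pgr was 5.37 (4.916 to 4.96). In p38α-lox PyMT arrays the glycolysis mean was 9.65 in replicate 3 (9.941 to 10) and the mesenchymal transition mean 4.913 in replicate 4 (5.252 to 5.299). Single genes set apart were the chaperone Calr in MMTV-Cre replicate 3 (11.11, others 10.51 to 10.6) and Trp63 in MMTV-Cre replicate 4 (5.813, 4.794 to 4.966). With PyMT they were Rps14 in PyMT replicate 4 (11.34, 12.11 to 12.21) and Car9 in PyMT replicate 2 (9.021, 6.882 to 7.204).

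In the interaction, age differed with PyMT and cannot be told apart from it. The p38α-lox difference with PyMT minus that without it passed camera for 10 lists. It was above 0 for glycolysis and hypoxia (0.651), the unfolded protein response (0.624), hormone-sensing markers (0.786), cholesterol synthesis (0.39), cell cycle (0.294), oxidative phosphorylation (0.243) and ribosomal protein genes (0.155). It was below 0 for inflammatory NF-kB (−0.775), milk and alveolar (−0.543) and interferon-stimulated genes (−0.373). With each of the 16 arrays left out in turn, glycolysis and the unfolded protein response passed in all 16 fits, ribosomal genes in 15, hormone-sensing and oxidative phosphorylation genes in 14, NF-kB in 13, cholesterol and milk in 11, interferon in 7 and cell cycle in 6. Values furthest from those above were −0.0333 and 0.633 for cell cycle without p38α-lox replicates 2 and 4, 0.245 for hormone-sensing and −0.237 for milk without MMTV-Cre replicate 2, and 0.0696 for ribosomal genes without PyMT replicate 4. They were −0.193 and −0.627 for interferon without PyMT replicate 1 and MMTV-Cre replicate 2, and 0.129 for oxidative phosphorylation without p38α-lox replicate 1. For cholesterol it was 0.238 without p38α-lox replicate 2. For NF-kB they were −1.05 and −0.537 without p38α-lox PyMT replicate 1 and p38α-lox replicate 2. The p38α-lox difference without PyMT turned between the lower and higher title ranges for cell cycle (−1.35 and 1.09), NF-kB (0.985 and −0.149), milk (0.75 and −0.219), oxidative phosphorylation (−0.485 and 0.217) and ribosomal genes (0.0592 and −0.0295). With an estimated correlation 0 lists passed, with 2 at an unadjusted p under 0.05, and with fry 0, with 0 under 0.05.

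The lower unfolded protein response and glycolysis means in p38α-lox than in MMTV-Cre arrays (−0.722 and −0.55) were tested against differences in sampling. Removing the slope within groups on the immediate early genes, which respond to the stress of cell isolation, left −0.696 and −0.46, with no overlap of the groups (exact permutation p = 0.0286 each). Removing that on the hormone-sensing list left −0.52 and −0.38 (exact permutation p = 0.0286 and 0.0571), and without MMTV-Cre replicate 2, the array with the highest hormone-sensing mean, camera kept both lists (−0.648 and −0.45; adjusted p = 1.13e-10 and 5.01e-09). Removing that on array quality, read as the median correlation with the other arrays, left −0.668 and −0.434 (exact permutation p = 0.0571 each), and without the 2 arrays of lowest correlation camera kept both (−0.715 and −0.512; adjusted p = 1.01e-08 and 3.07e-07), while the NF-kB, interferon and cholesterol calls ended (0.435, 0.0793 and 0.57). The immediate early means differed by 0.219 between the groups, with slopes of −0.119 and −0.413. Removing such slopes could change little, so this test cannot decide on isolation stress. The values argue against the hormone-sensing share as the whole cause for the unfolded protein response, where the groups still did not overlap. Where the exact permutation p was 0.0571 the groups overlapped, and the kept camera calls rest on the preset correlation. Array quality, and the hormone-sensing share for glycolysis, therefore stay undecided. Over all alternatives the adjusted p ran up to 0.291 and 0.444, so chance stays open beside an effect of the p38α allele.

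The higher ribosomal protein mean in p38α-lox PyMT than in PyMT arrays (0.17) was set against brightness and against 1 array. Genes of the same mean level, the 20 nearest for each member, shifted by 0.0455, and the list lay at percentile 100 of 10000 matched random lists, which argues against a shift of all bright probe sets. Without PyMT replicate 4, the array with the low Rps14, the mean was 0.0844 with camera adjusted p = 0.00745 (range over all alternatives 4.22e-09 to 0.851). That array cannot be told apart from an effect of the p38α allele as the source of much of the difference, because about as much of it was lost without the array as remained.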

How the results depend on the processing

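The alternatives without the 2 arrays of lowest median correlation and with the title-number covariate were chosen after seeing the data. For p38α-lox without PyMT, 0 genes became 1 with no filter, 8 with arrayWeights and 0 (without MMTV-Cre replicate 2) to 4 (without MMTV-Cre replicate 1) with 1 array left out. With PyMT, 0 became 5 with arrayWeights and 0 (without PyMT replicate 1) to 3 (without PyMT replicate 2); for the interaction it stayed 0 with each array left out. Between PyMT and MMTV-Cre, 182 genes became 1268 with arrayWeights, which included all 182, 55 with only the compared arrays (48 shared), 111 without the 2 arrays (87 shared) and 49 to 443 with 1 array left out (PyMT replicates 1 and 2). Between p38α-lox PyMT and p38α-lox, 112 became 1416 with arrayWeights, which included all 112, 169 with only the compared arrays (79 shared) and 26 to 194 with p38α-lox PyMT replicate 3 or 1 left out. Of the lists, the 6, 1 and 8 called for p38α-lox without PyMT, with PyMT and for PyMT without p38α-lox became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. With 1 array left out they were 3 (without MMTV-Cre replicate 4) to 8 (without p38α-lox replicate 4), 1 to 9 (without p38α-lox PyMT replicate 1) and 7 to 11. The 1 list with PyMT became 2 with the mean of all probe sets of a gene and 4 without the 2 arrays. Of 40 named genes called between PyMT and MMTV-Cre, 8 (Car12, Col9a1, Ecscr, Hbegf, Pdk4, S100a8, Saa1 and Wap) stayed called in all 18 alternatives and 0 changed sign in any. The other alternatives left the counts within 1.5 times those reported. Leaving arrays out reduces the number compared and arrayWeights rests on weights from 0.206 to 4.36; beyond this, the cause was not tested. The number of arrays limits the precision of all counts.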

Other observations

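In this part the tests of carried-over basal cells, of a lower luminal share, of exchanged labels and of proliferation were chosen after the results were seen. Further genes called between PyMT and MMTV-Cre arrays belong to lists whose mean was not shifted by camera. Of the mammary transcription factors (list adjusted p = 0.585), Lmo4 fell by 1.92 on the log2 scale, while Tfap2c rose by 1.79 ± 0.4 and Cebpb, which drives alveolar development, by 1.56 ± 0.353. Of the oxidative stress genes (adjusted p = 0.496), the quinone reductase Nqo1 rose by 2.50 ± 0.466 and catalase Cat by 1.28 ± 0.224. Of the EGF family genes (adjusted p = 0.962), the ligand Hbegf rose by 1.92 ± 0.313. The sterol reductase Dhcr7 rose by 2.49 ± 0.44. Of 18 alternatives, the call ended in 12 for Cebpb, 9 for Tfap2c, 8 for Lmo4, 4 for Nqo1, 2 for Cat, 1 for Dhcr7 and 0 for Hbegf; with the mean of all its probe sets Cebpb differed by 0.67.

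The higher basal and myoepithelial list in PyMT than in MMTV-Cre arrays (0.94) was set against cells of other types in the sort. Basal keratins and Trp63 were 2.31 higher (exact permutation p = 0.0286), as in Krt14 (9.75 against 7.21), while the contractile basal genes were 0.439 higher (exact permutation p = 0.371), with Acta2 at 9.87 against 8.66 and Myh11 at 5.86 against 6.25. Over the 8 arrays without PyMT the contractile mean followed the keratin and Trp63 mean (slope 0.722, r = 0.972), and from this line, extended beyond the keratin and Trp63 means it was fitted on (5.56 to 8.04, against 8.40 to 9.61 in PyMT arrays), the PyMT arrays lay −1.24 off on average (−1.32 to −1.1, against −0.157 to 0.334 in the 8). That argues against carried-over basal cells of the kind in the other arrays as the whole cause. A lower luminal share cannot be told apart from other causes. Over all alternatives the luminal keratin and junction list differed by −0.42 to −0.15 (camera or fry adjusted p from 0.011 to 0.817). The hormone-sensing list differed by −0.84 to 0.06 (from 0.00188 to 0.888), and the luminal progenitor list by 0.05 to 0.34 (from 0.0331 to 0.888). None of these lists was called as reported. Of the lists of the 6 other cell types, 1 (fibroblast) had a change of at least 50% of that of the basal list, and the basal list exceeded their mean change by 0.728, but with overlapping groups (exact permutation p = 0.0857). In MMTV-Cre arrays 6 of 13 endothelial, 6 of 10 lymphocyte and 6 of 14 myeloid markers lay above the array median. For basal markers it was 13 of 14, and for fibroblast, adipocyte and erythroid markers 8 of 10, 5 of 6 and 4 of 5. Weak markers can miss a rise, so the count of lists is a weak test. A change of luminal cells with the oncogene or with age may also contribute and was not tested.

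Whether chance could give such counts was tested by regrouping the arrays. Between PyMT and MMTV-Cre, 182 genes were called and at most 16 in the other splits, so 1 of 35 splits gave as many, and with p38α-lox 112 against at most 0 in the others, again 1 of 35. This is the smallest share that 35 splits can give (0.0286). It argues against a random grouping of the compared arrays, but not against another structure of the samples. A split of the arrays without PyMT that is not by genotype called 199 genes. For p38α-lox 0 genes were called by limma with and without PyMT and for the interaction (516, 690 and 406 at an unadjusted p under 0.05). With a count of 0 all 35, 35 and 100 splits give as many by construction, which says nothing about chance; the highest counts of the others were 3, 199 and 265. For lists called by camera, chance cannot be excluded: 21 of 35 splits gave the 6 of p38α-lox without PyMT (at most 11), 34 of 35 the 1 with PyMT (at most 16), 18 of 100 the 10 of the interaction (at most 14), 16 of 35 the 8 of PyMT without p38α-lox (at most 13) and 9 of 35 the 9 with it (at most 11). The 100 groupings for the interaction include the real one, and the others mix arrays with and without PyMT. The PyMT difference can enter these, so they are no clean reference for it. The split with 199 genes set MMTV-Cre replicates 1 and 2 and p38α-lox replicates 3 and 4 against the rest, that is, lower title numbers of one genotype with higher ones of the other. It points to a structure of these samples that crosses genotype with the title ranges, whose source is not given in the sources used here.

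Mapk14 and the cell cycle list follow the same split. On its first side, MMTV-Cre replicates 1 and 2 and p38α-lox replicates 3 and 4, Mapk14 was 7.106, 7.43, 7.906 and 8.159, and on the other 5.555 to 6.791; the cell cycle means were 7.083 to 7.661 against 5.661 to 6.744. As labelled, Mapk14 was lower in p38α-lox in the lower title range (−0.687) and higher in the higher one (2.24). One hypothesis is that genotype labels were exchanged between the MMTV-Cre and p38α-lox arrays of the higher range. Of the 6 Mapk14 probe sets, 3 turned as this would need and 3 did not. In MMTV-Cre arrays the former had means of 6.53, 6.40 and 5.255 and the latter 4.77, 5.77 and 4.63. Array medians ran from 4.63 to 4.88. The exchange also needs Mapk14 to follow the genotype, which the probe set used did not in PyMT arrays (7.232 with p38α-lox against 7.203). The other 5 were lower with p38α-lox there, with differences from −0.378 to −0.0129 (smallest exact permutation p = 0.229). The unfolded protein response (−0.611 and −0.833) and glycolysis (−0.683 and −0.417) differences kept their direction in both ranges as labelled. An exchange cannot be told apart from other causes. The probe sets do not move together, some of them lie near the array medians, and each range holds 2 arrays per group. A dependence of Mapk14 on proliferation was tested as well. Removing its slope on the cell cycle list within groups with PyMT (−0.0982 ± 0.229) left 2.35. That slope was smaller than its error, so its removal could change little. Its upper limit accounted for 0.746, which speaks only to a dependence as weak as the one in those arrays. The rule of this test was revised after its values were seen. A dependence found only without PyMT stays open, since its slope can be read only from the arrays that show the pattern. The labels were kept as given. If they were exchanged, every difference here that uses arrays without PyMT could change, among them the lower unfolded protein response and glycolysis means and the counts of 182 and 112 genes.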
